A study of Homo sapiens with 2 samples.

How the data were processed

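RNA sequencing libraries of SUM-159 cells were compared, 1 labelled PD-L1L2-SE deficient and 1 labelled sgVector. Per the labels' protocols, RNA was enriched for poly(A) tails or depleted of ribosomal RNA, fragmented, copied into cDNA, joined to adaptors and amplified by PCR, and the labels give the molecule as polyA RNA. Per the submitters' processing notes, Subread and featureCounts 1.6.4 were used with the builds GRCh37 and hg19. The aligner, the annotation release and whether counting used strand are not given in the sources used here, so overlapping and antisense genes are uncertain.

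The authors deposited RPKM values, reads per kilobase of gene length per 1000000 reads on genes, with 1 column per library, beside exon coordinates and gene length per the file headers. RPKM times length summed to the same total in both columns and its steps gave whole reads for 100% of values (within 1e-06 of a read). From these steps 16381546 reads were recovered for the deficient library and 16206675 for the sgVector library, which served for intervals and read minimums. A value of 0 allows up to 3 reads, a floor of 0.183 reads per 1000000 in the deficient and 0.185 in the sgVector library.

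Of 60880 rows, 56858 (93.4%) matched GENCODE release 29 by gene identifier, from which gene types and the GC content of the longest transcript were taken, with current symbols from a gene name table. No coordinates were taken from that release, which is on another build. The 41 rows of the pseudoautosomal copies on chromosome Y were left out of the comparison. GC content was known for 98.9% of the genes past the floor.

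The main value was the log2 ratio of (RPKM + 0.1) in the deficient library over (RPKM + 0.1) in the sgVector library, for genes with a mean of at least 1 RPKM (13552 genes, 10576 of them protein-coding). This scale understates the change of genes with low values. Fold changes in the text are ratios of the libraries' read shares without the pseudocount, with a 95% Clopper-Pearson interval. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Higher and lower calls used a log2 ratio of at least 1 or at most -1. No p-values were computed across genes, since there was 1 library per group.

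Gene lists, 26 in all, and the rule for named genes were fixed before the data were examined. A list with at least 5 measured members was described by its median and by the percentile of that median among 10000 random lists of the same size, matched in 10 classes of mean RPKM, with a fixed seed. A list stood apart below the percentile 2.5 or above 97.5. For 3 lists with fewer members values alone are given. Genes were named if they were CD274, PDCD1LG2 or genes of known symbol within 1 Mb of them and past the floor, if they were among the 10 highest or 10 lowest ratios of protein-coding genes with at least 50 reads over both libraries, or if they were among the 3 highest or 3 lowest members of a list. Intervals of genes named for their rank do not account for that choice.

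Alternatives fixed beforehand were pseudocounts of 1 and 0.01, centring on the median, rescaling to TPM, trimmed mean of M values (TMM) and upper-quartile scaling, removal of mitochondrial genes, floors of 5, 0.5 and none, protein-coding genes alone, thresholds of 1.5-fold and 4-fold, intervals wholly past 2-fold, unmatched random lists, lists without their farthest member and a window of 5 Mb. Added after the data were seen were lowess corrections (share 0.3) of the log2 ratios on GC content and then on log10 length, fitted on protein-coding genes, a minimum of 50 reads for the counts of genes, TMM for the 9p24.1 neighbours, the interval rule on protein-coding genes, and lists without members that another list holds. Scaling alternatives kept the genes past the floor on deposited RPKM. TMM trimmed 30% of the log ratios and 5% of the mean levels at each end.

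The steps were tested on simulated data. Among 200 protein-coding genes changed by known folds, 99.0% of the 3-fold genes and 1.00% of the 1.5-fold genes passed 2-fold. The work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.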

Results

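Gene expression was measured by RNA sequencing in SUM-159 cells, a human triple-negative breast cancer cell line. One library came from cells deficient for PD-L1L2-SE, the super-enhancer that the study's title ties to the joint expression of PD-L1 and PD-L2, and 1 library from cells given the sgVector control. The deposited RPKM values corresponded to 16381546 reads on genes in the deficient library and 16206675 in the sgVector library, with at least 1 read on 27115 and 27725 genes. With 1 library per group no difference below has a replicate check. The intervals given are 95% Clopper-Pearson intervals of the read ratio and cover counting error only.

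Loss of the element was set against the expression of the genes it is named for. CD274, which encodes PD-L1, was 10.3-fold lower in the deficient library (95% interval 7.59 to 14.2), at 0.698 RPKM from 47 reads against 7.16 RPKM from 477 reads. PDCD1LG2, which encodes PD-L2, was 4.48-fold lower (3.24 to 6.32), at 1.19 RPKM from 46 reads against 5.32 RPKM from 204 reads. Both proteins are ligands of the T-cell inhibitory receptor PD-1. On the log2 scale with the pseudocount of 0.1 RPKM the ratios were -3.19 for CD274 and -2.07 for PDCD1LG2. In hg19 coordinates CD274 (ENSG00000120217) lies on chromosome 9 from 5450503 to 5470566 and PDCD1LG2 (ENSG00000197646) from 5510570 to 5571254. The position of the removed element within 9p24.1 is not given in the sources used here. With a pseudocount of 1 RPKM the CD274 log2 ratio was -2.27.

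The genes around the pair were lower in the deficient library as well, by smaller amounts. Of the 11 other protein-coding genes within 1 Mb with a mean of at least 1 RPKM, 10 had a log2 ratio below 0 and 3 were at least 2-fold lower, with a median of -0.88. SLC1A1, a glutamate transporter gene, was 2.94-fold lower (2.36 to 3.69), CDC37L1 2.82-fold lower (2.28 to 3.51) and UHRF2 2.21-fold lower (1.91 to 2.57). RCL1, ERMP1, PLGRKT, KIAA2026, RANBP6, AK3 and RIC1 had log2 ratios of -0.96, -0.89, -0.88, -0.77, -0.69, -0.62 and -0.56. RIC1 and ERMP1 overlap, so their reads are uncertain. JAK2, which encodes a kinase of cytokine signalling, had 302 reads against 276 and a log2 ratio of 0.11, whose sign changed with a GC and length correction (-0.07). The processed pseudogene SELENOTP1, which can take reads of its parent gene, stood at 0.24. Within 5 Mb 16 of 17 genes were below 0, again with a median of -0.88. The lower values extended to the end of the chromosome arm, from WASHC1, which has close paralogs, to LURAP1L at 12.8 Mb, where 18 of 19 protein-coding genes other than the pair were below 0, against a median of -0.08 over 79 genes on the rest of 9p. This boundary was drawn after the values were seen.

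**Figure D1:**
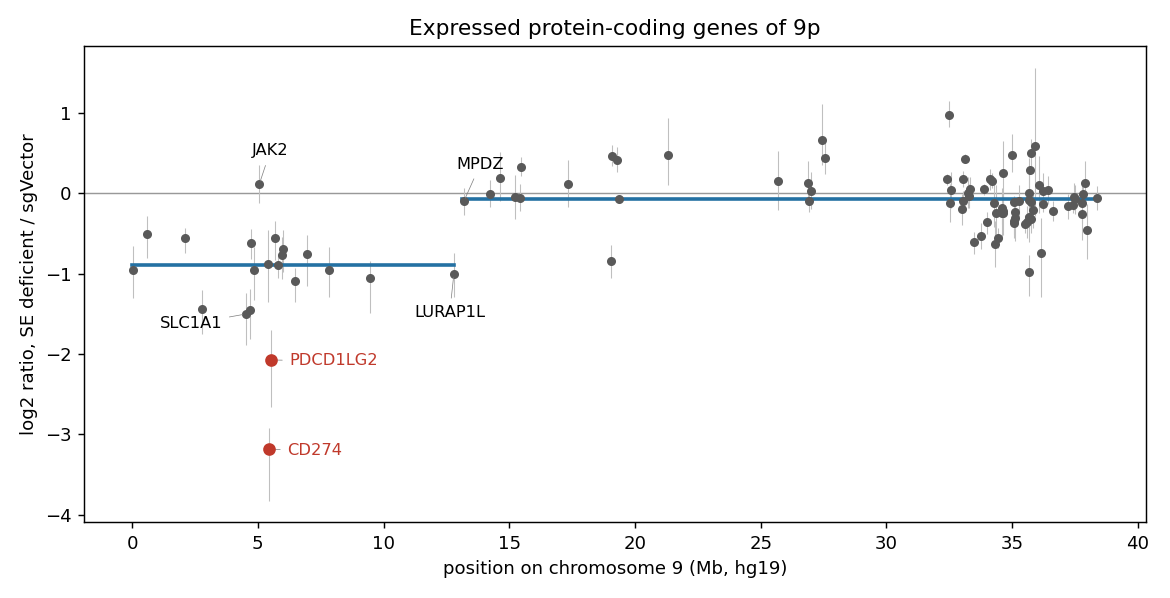
Log2 ratio of the deficient over the sgVector library (y axis) against position on chromosome 9 in Mb, hg19 (x axis), for protein-coding genes of 9p with a mean of at least 1 RPKM. Points are genes, thin lines their 95% counting intervals and blue lines the medians of 2 stretches, -0.89 and -0.08; CD274 and PDCD1LG2 (red) lie at -3.19 and -2.07, below the other genes of the first stretch.

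Across the transcriptome, 411 of 13552 genes with a mean of at least 1 RPKM were at least 2-fold higher in the deficient library and 636 were at least 2-fold lower. Among the 10576 protein-coding genes the numbers were nearly equal, 222 higher and 219 lower. The surplus of lower genes lay in non-coding classes. Of 312 small RNA genes 35 were higher and 112 lower, and of 1099 long non-coding RNA genes 51 were higher and 159 lower. No small RNA type took more than 0.0072% of the reads of either library, so these small RNA calls rest on few reads per gene. In simulated libraries that differed by counting noise alone, 125 of 13645 genes came out at least 2-fold higher and 100 lower, and 1 of all these was protein-coding. With the whole 95% interval past 2-fold, 165 genes were higher and 160 lower, so the surplus of lower genes did not remain.

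The 10 protein-coding genes with the highest ratios had between 2 and 151 reads in the sgVector library. NEO1, which encodes the netrin and RGM receptor neogenin, had 1683 reads against 22 and was 75.7-fold higher (49.8 to 121). DOCK3, a guanine nucleotide exchange factor gene, had 1668 reads against 30 and was 55.0-fold higher (38.4 to 81.8). CES1, a carboxylesterase gene with a near-identical pseudogene, was 15.1-fold higher (12.8 to 17.96), and the heparan sulfate proteoglycan gene GPC6 20.4-fold higher (11.7 to 38.8). The adhesion molecule gene CADM3 was 19.3-fold higher (14.4 to 26.4), and ACKR1, an atypical chemokine receptor gene that overlaps it, 31.2-fold higher (14.9 to 78.6). CPVL was 19.4-fold higher (9.61 to 45.8), CHST1 19.1-fold higher (8.53 to 53.2) and the olfactory receptor gene OR52E2 13.3-fold higher (5.41 to 42.2). ORM1, an acute-phase protein gene with the close paralog ORM2, had 71 reads against 2, a ratio of 35.1 (9.37 to 296).

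The 10 lowest log2 ratios of protein-coding genes ran from -5.77 for PAGE5 to -2.85 for VCX. CSF3, which encodes the growth factor G-CSF, had 52 reads against 801 and was 15.6-fold lower (11.8 to 21.03). The Wnt antagonist genes SOST and DKK1 were 10.2-fold lower (8.84 to 11.8) and 8.22-fold lower (5.61 to 12.4), SOST from 2079 reads to 206. UNC5B, a netrin receptor gene, was 12.6-fold lower (9.23 to 17.5) and AZGP1 12.2-fold lower (7.80 to 20.02). RARRES2, which encodes the chemoattractant chemerin, had 1 read against 114, a ratio of 115 (20.3 to 4591). The cancer-testis genes PAGE5 and VCX, both members of families of similar genes, had 2 reads against 172, a ratio of 86.9 (23.7 to 724), and 11 against 89, a ratio of 8.18 (4.36 to 17.0). The homeobox gene DUXA had 0 reads against 54, at least 18.2-fold lower when 3 reads are set for 0. CD274 was the eighth lowest of the protein-coding genes by log2 ratio.

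**Figure D2:**
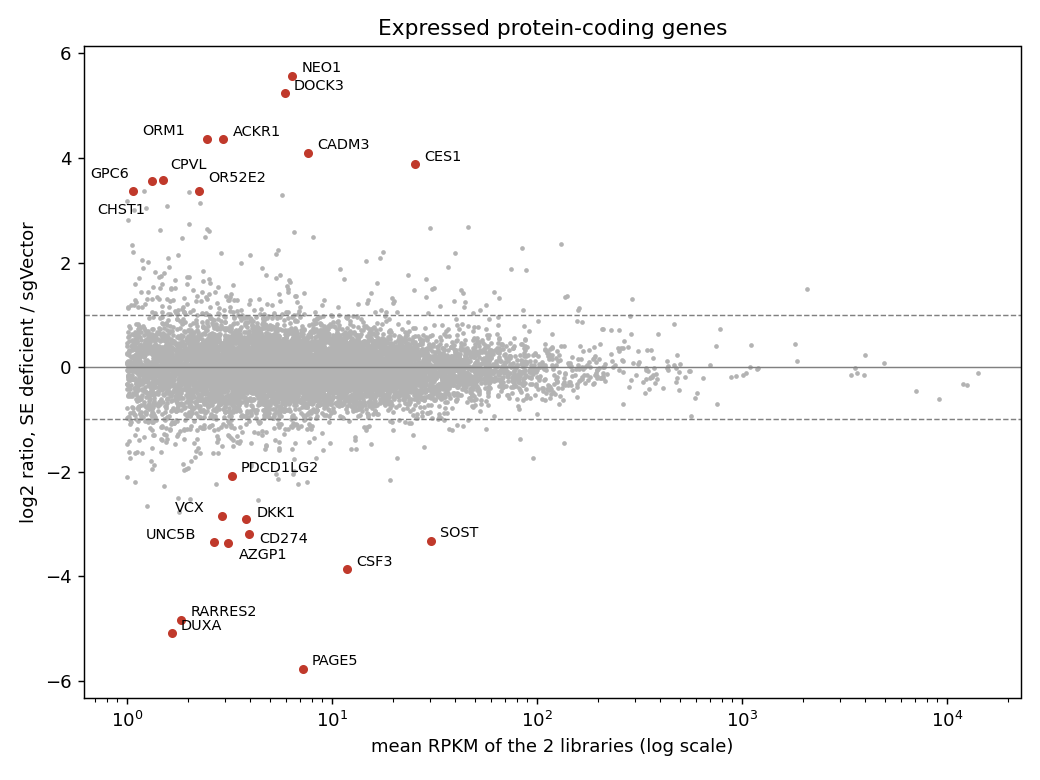
Log2 ratio of the deficient over the sgVector library (y axis) against the mean RPKM of the 2 libraries (x axis, log scale) for protein-coding genes with a mean of at least 1 RPKM, chromosome Y left out. Dashed lines mark 2-fold; red points are the 10 highest and 10 lowest genes with at least 50 reads and PDCD1LG2, from NEO1 at 5.58 to PAGE5 at -5.77.

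Gene groups of immune signalling stood higher in the deficient library. Interferon-stimulated genes had a median log2 ratio of 0.51, above all 10000 random lists matched on mean expression. Of 36 measured members 9 were at least 2-fold higher and 0 lower, led by the antiviral genes RSAD2 at 10.8-fold higher (7.46 to 16.3), IFIT2 at 4.56-fold (4.25 to 4.89) and IFIT3 at 3.70-fold (3.49 to 3.93). LIPA overlaps IFIT2 and IFIT3 in the annotation. IFI35 and IFI6 went the other way, at -0.63 and -0.45. USP18 stood at -0.50 from 39 reads against 56, with an interval that spanned no change (-1.17 to 0.08 in log2). MHC class I genes had a median of 0.31, also above all 10000 random lists, although 0 of 21 members reached 2-fold. CANX, an endoplasmic reticulum chaperone gene, stood at 0.86, and HLA-B and HLA-F, whose reads are uncertain because HLA genes resemble each other, at 0.71 each. TAPBPL, PSME2 and PSME1 stood at -0.66, -0.32 and -0.32.

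Cytokine genes moved in both directions. The list of NF-kB targets, cytokines and chemokines had a median of 0.24 (percentile 99.98 of the random lists), with 5 of 30 members at least 2-fold higher and 4 at least 2-fold lower. The chemokine genes CCL2, CXCL1 and CCL5 were 13.4-fold (6.84 to 30.03), 3.73-fold (1.99 to 7.49) and 2.47-fold (2.38 to 2.56) higher, CCL5 at 415 against 168 RPKM. CSF3, CSF2 and TNFAIP6 were lower, with log2 ratios of -3.87, -2.23 and -1.14. JAK-STAT genes had a median of 0.23 (percentile 99.8) and 1 of 21 members past 2-fold, the feedback inhibitor gene SOCS1 at 2.53-fold lower (1.82 to 3.56), which a pseudocount of 1 or the GC and length correction brought just short of 2-fold. The receptor genes IL6ST, LIFR and IFNGR1 stood at 0.91, 0.74 and 0.53. Other immune checkpoint ligands and surface immune regulators had a median of 0.00 (percentile 71.3), with 0 of 21 members past 2-fold. Among them FAS, CD40 and ULBP3 stood at 0.80, 0.66 and 0.51, and PVR, CD70 and TNFRSF14 at -0.75, -0.65 and -0.61. The ULBP3 interval spanned no change (-0.35 to 1.47 in log2).

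Mitotic genes stood lower, with a median log2 ratio of -0.31 (percentile 0.07) and 23 of 28 members below 0, none of them by 2-fold. AURKB, CENPA and PLK1, which act in chromosome segregation, stood at -0.88, -0.80 and -0.62. HMMR and the proliferation marker gene MKI67 stood at 0.47 and 0.45. DNA replication genes did not stand apart, with a median of -0.06 (percentile 46.7). The 9p24.1 list, chosen for its place around CD274 and PDCD1LG2, had a median of -0.89 (percentile 0.01).

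Integrins and adhesion receptors had a median of 0.20 (percentile 98.3), with MCAM 2.11-fold higher (1.71 to 2.61), ITGB8 at 0.75 and ITGA2 at 0.69, and ALCAM, VCAM1 and ITGB5 at -0.73, -0.65 and -0.38. This list no longer stood apart after a GC and length correction (percentile 77.5), with a floor of 5 RPKM (93.0), with no floor (91.7) or without ITGB3, which the mesenchymal list also holds (95.8). In all, 7 of 23 lists stood apart, counting the 9p24.1 list, 5 above and 2 below. Of 100 random lists of 30 genes, 2 did. That share follows from the cutoffs, and it gives no rate for lists of genes that vary together.

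Some lists that did not stand apart held single genes with large ratios. Among mesenchymal and matrix genes (median -0.19, percentile 6.40) 5 of 29 were at least 2-fold lower, among them the microfibril gene FBN1 at 3.24-fold (2.82 to 3.73), the crosslinking enzyme gene LOXL2 at 2.59-fold (2.499 to 2.681) and the type I collagen gene COL1A1 at 2.54-fold (2.37 to 2.72). The basement membrane collagen gene COL4A1 was 2.499-fold higher (2.24 to 2.79), and a pseudocount of 1 brought it just short of 2-fold. COL4A1 lies on chromosome 13, where the median log2 ratio of 180 protein-coding genes was 0.46. Among unfolded protein response and ATF4 target genes (median -0.07, percentile 40.7) 4 of 24 were at least 2-fold lower and 0 higher, with DDIT3 at 2.98-fold (2.44 to 3.65) and the serine and asparagine synthesis genes PHGDH and ASNS at 2.78-fold (2.602 to 2.967) and 2.04-fold (1.89 to 2.21), ASNS falling just short of 2-fold under several scalings. Among epithelial genes (median -0.27, percentile 4.93) the desmosome gene DSP was 4.15-fold lower (3.41 to 5.07) and CLDN1 2.30-fold lower (1.85 to 2.87), while KRT17 was 2.12-fold higher (1.78 to 2.52). FOS was 4.90-fold higher (3.93 to 6.15) and FOSL1 2.29-fold lower (2.13 to 2.46) in an immediate-early list with a median of -0.07 (percentile 42.8). The GC and length correction brought FOSL1 just short of 2-fold.

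PMAIP1, which encodes the pro-apoptotic protein NOXA, was 4.16-fold higher (3.57 to 4.86), while the cell cycle inhibitor gene CDKN1A was 2.20-fold lower (1.98 to 2.46). The GC and length correction brought CDKN1A just short of 2-fold. The p53 target list had a median of -0.01 (percentile 62.3). CCN2 was 2.43-fold higher (2.18 to 2.72) among YAP targets (median 0.11, percentile 93.1). The hexokinase gene HK2 was 2.40-fold higher (2.28 to 2.52) among hypoxia and glycolysis genes (percentile 74.2). MVK was 2.38-fold lower (1.93 to 2.96) among cholesterol genes (percentile 30.5). The apoptosis list, of BCL2 family and death receptor genes, does not hold PMAIP1, which is in the p53 list. This apoptosis list and the enhancer coactivators had 0 members past 2-fold and percentiles of 64.5 and 87.8. The median log2 ratio of the immune ligand, immediate-early, DNA replication, p53, apoptosis, hypoxia and unfolded protein lists changed sign with the scaling or the GC and length correction.

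**Figure D3:**
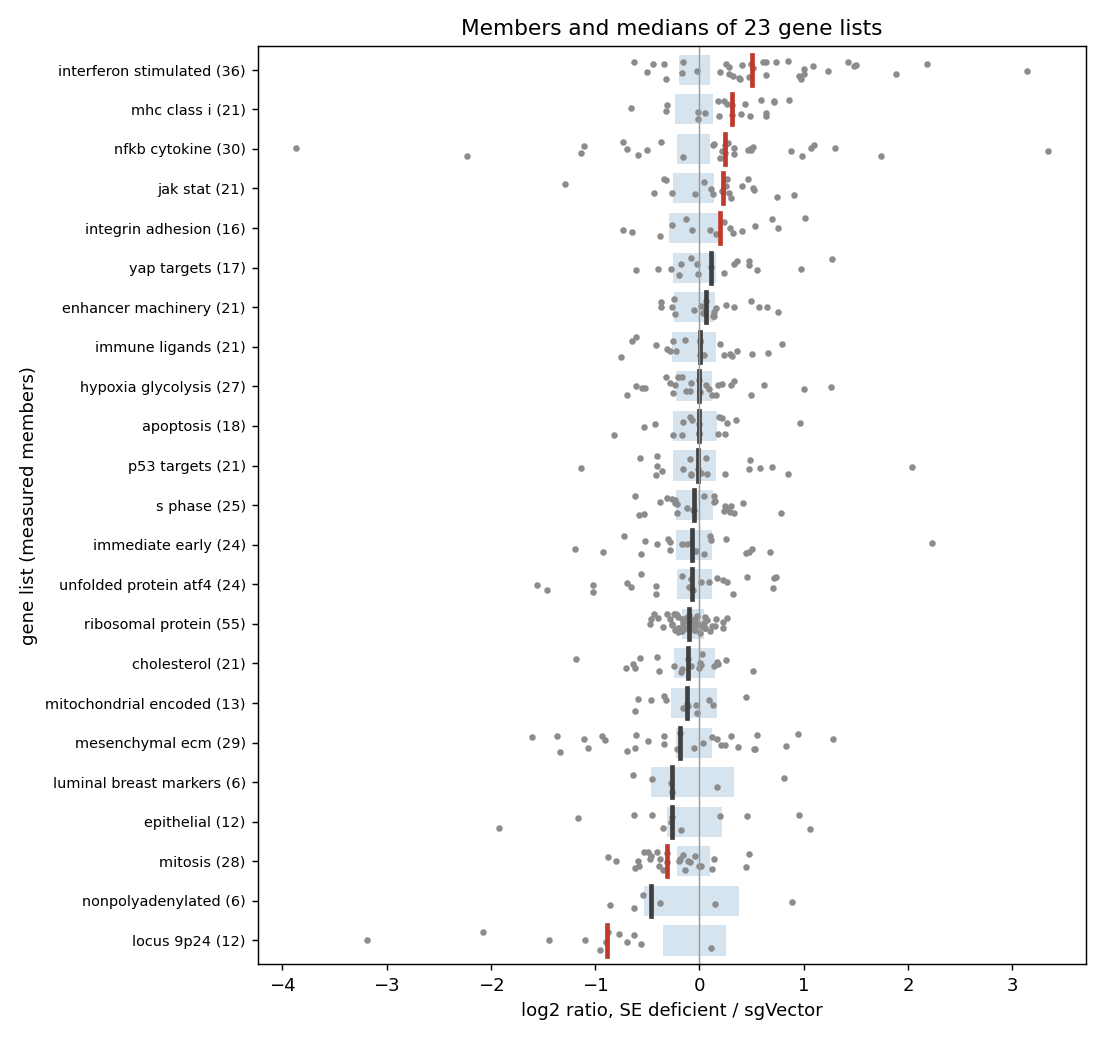
Log2 ratio of the deficient over the sgVector library (x axis) for the measured members of 23 gene lists (y axis, number of members in brackets). Grey points are genes, vertical bars list medians (red where the list stood apart) and blue bands the central 95% of medians of 10000 matched random lists; interferon-stimulated genes at 0.51 and the 9p24.1 genes at -0.89 lie at the ends.

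The libraries differed in composition along with these groups. Genes of the mitochondrial genome took 6.50% of the reads in the deficient library and 7.99% in the sgVector library, with a list median of -0.12 (percentile 28.1), and cytosolic ribosomal protein genes had a median of -0.10 (percentile 20.3). The list set up for histone and small RNA genes without a poly(A) tail had a median of -0.46 over 6 members (percentile 4.35). Whether these 6 members lack a poly(A) tail was not checked. The median over all small RNA genes past the floor was -0.61, from few reads per gene. The ratio also followed base composition. With protein-coding genes split into 5 equal classes, the class of lowest GC content had a median of 0.14 and the class of highest GC content -0.20, and from the shortest to the longest class the median went from -0.16 to 0.09. After both trends were removed the interferon-stimulated and MHC class I lists still lay above and the mitotic list below the range that marks a list as apart. Leukocyte markers were scarce, with 548 reads over the list in the deficient library against 393, mostly of CD14 (476 against 337). Endothelial markers had 203 reads against 195, with ERG alone past the floor, and MHC class II genes 225 against 219, with HLA-DMA alone past the floor at -0.84. Luminal breast markers had a median of -0.27 over 6 members (percentile 14.5).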

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

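The corrections for GC content and length, the minimum of 50 reads, TMM scaling for the 9p24.1 neighbours, the interval rule on protein-coding genes and the removal of members shared between lists were chosen after seeing the data. CD274 and PDCD1LG2 were lower under all 8 alternatives tried for each, and 2 of these 16 values lay outside the counting interval, CD274 (-2.27) and PDCD1LG2 (-1.53) with a pseudocount of 1, as a larger pseudocount shrinks the ratios of low genes. The median of the 9p24.1 neighbours stayed between -0.92 and -0.80. The counts of genes depended most on the floor and the threshold. Against 411 higher and 636 lower they were 215 and 344 with a pseudocount of 1, 115 and 152 with a floor of 5 RPKM, 642 and 1138 with a floor of 0.5 RPKM and 2575 and 3711 with no floor. They were 222 and 219 for protein-coding genes alone, 1123 and 1703 at 1.5-fold, 85 and 131 at 4-fold, 165 and 160 with the interval wholly past 2-fold, and 139 and 110 with that rule on protein-coding genes. With at least 50 reads 278 genes were higher and 346 lower. Each of these settings changes how many genes enter or pass by its own construction.

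Of 322 list percentiles under alternatives 313 kept their call. Centring shifts all genes alike, so it could not change a percentile. The other scalings shift most genes almost alike, so their unchanged calls add little. The integrin list lost it after the GC and length correction (percentile 77.5), with a floor of 5 RPKM (93.0), with no floor (91.7) and without its member shared with another list (95.8). YAP targets stood apart after that correction (98.6) and with no floor (97.9), and mesenchymal genes with a floor of 5 RPKM (0.710). The list set up for genes without a poly(A) tail did so among protein-coding genes alone (1.52) and with unmatched random lists (2.48). The cause was not tested for any of these. The interferon median ranged from 0.40 to 0.58, and the mitotic median from -0.34 to -0.24. For other named genes past 2-fold, 50 of 400 values lay outside the counting interval, 32 of them with a pseudocount of 1, and 0 changed sign. The call itself ended under at least 1 alternative for 12 of these 50 genes, 10 of them with a pseudocount of 1. The GC and length correction, which raises GC-rich genes, ended it for FOSL1, from -1.19 (-1.30 to -1.09) to -0.97 (-1.08 to -0.87), for CDKN1A, from -1.13 (-1.30 to -0.98) to -0.94 (-1.11 to -0.79), and for SOCS1, from -1.29 (-1.83 to -0.86) to -0.98 (-1.52 to -0.55). ASNS, at -1.03, lost it with centring (-0.97), TPM (-0.98), TMM (-0.95), upper-quartile scaling (-0.98) and a pseudocount of 1 (-0.98), and ADM and MCAM without mitochondrial genes (0.98 and 0.996). Among listed genes short of 2-fold, 7 passed it under some scaling or that correction. Depth limits genes such as PAGE5, ORM1, RARRES2 and DUXA, with 0 to 2 reads in 1 library.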

Other observations

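The runs of neighbouring genes, the chromosome medians and the tests in this part were chosen only after the results were seen. In 100 random orders of the genes over the genome, the medians of runs of 20 consecutive expressed protein-coding genes stayed between -0.57 and 0.52. In the true order the highest was 0.80, on chromosome 11 from CASP1 to DLAT (hg19 104896170 to 111935114), where 19 of 20 genes were above 0; after GC and length correction it was 0.67. Chromosome 13 had the highest median of the chromosomes, 0.46 over 180 protein-coding genes, or 0.35 after correction, and chromosomes 12 and 22 had -0.29 and -0.31, or -0.30 and -0.22. The run from LRP1 to METTL1 on chromosome 12 had a median of -0.69 with 20 of 20 genes below 0, and contains DDIT3, the lowest of the ATF4 target genes.

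The genes of terminal 9p, from WASHC1 to LURAP1L, had a median of -0.89 over 19 genes besides CD274 and PDCD1LG2, and the run from WASHC1 to PTPRD, with the pair included, was the lowest of all such runs (-0.92). A GC or length trend is argued against, since the corrected median was -0.91 (bootstrap 95% range over genes -1.02 to -0.79). An effect reaching no farther than 1 Mb from the pair is argued against by the 6 genes between 1 and 5 Mb away. Their median was -0.86 (bootstrap 95% range over genes -1.25 to -0.53, which treats neighbouring genes as independent). The limits of 1 and 5 Mb were set before the data were examined, but this test was chosen after. These 6 genes belong to the segment and their low values were already known, so they are no independent check. A lost copy of the chromosome end in the deficient cells, or a gained one in the control cells, is a candidate explanation and could account for a part of the CD274 and PDCD1LG2 difference that is about the size of the neighbours' median. The reads of genes below the floor cannot decide it. Their pooled log2 ratio was -0.50 (-0.72 to -0.28) in this segment but also -0.43 (-0.59 to -0.27) on the rest of 9p, a difference of -0.069. The range of this difference, -0.45 to 0.31, subtracts opposite ends of the 2 intervals and is wider than a 95% interval. Only 4 such genes in the segment had at least 50 reads, and JAK2 at 0.11 does not follow the segment.

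The interferon-stimulated genes kept a median of at least 0.48 under the scalings tried. These shift most genes almost alike and by little, so they were no separate test of the list. Base composition and gene length did not account for its higher values. After the GC and length correction the list still lay above all random lists (percentile 100). A response to the loss of the element, to the handling of the cells or to a difference between the cell populations sequenced may each underlie it, and the design, with 1 library per group, leaves these untested.

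Single genes such as NEO1, DOCK3, CSF3 and SOST differed by more than 10-fold. Counting noise alone is argued against, since it gave 1 protein-coding gene past 2-fold in simulation against 441 observed. The simulation held no PCR duplicates and no variation between cultures or library preparations, so such variation was not tested. Copy changes of whole regions stay open for a part of them. For 249 genes with an interval past 2-fold, the log2 ratios of the nearest expressed genes on both sides were averaged. These averages had a median of 0.25 in the gene's direction (0.18 to 0.31), and 64 were at least 0.5. A single flank can carry an average, and genes past 2-fold can flank each other, as CADM3 and ACKR1 do. No such averages were taken for other genes. At NEO1, DOCK3, CSF3 and SOST a copy change that takes in the nearest expressed genes is argued against as the whole cause. These flanking genes stood between -0.56 and 0.43. Of the 10 highest and 10 lowest genes, 15 had both flanks with intervals short of 2-fold in the gene's direction. The others were CADM3, ACKR1, OR52E2, CD274 and VCX. Flanks were taken at any distance on the chromosome, so a copy change that leaves them out was not tested. A difference between the cells that founded the 2 populations was not tested.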
